A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

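The data were 4 two-colour arrays, each hybridised with 1 AAE13 culture and 1 ccdB control culture, with the dyes swapped on 2 of them per the labels. The labels describe 4 biological replicates per strain, RNA reverse transcribed from an oligo-dT primer and indirect labelling with Alexa dyes. The deposited table holds log2 ratios for 6256 probes, with 4 missing values. That the log base is 2 was inferred from the values and is not stated: the highest value, 16.61, lies just above the 16 bits of a scanner on that scale and would lie further beyond them on a natural or decimal log scale. That value came from 1 probe without a gene name on array 1. After centring on array medians, the probe was at 16.18 there and at -3.84, -0.17 and -2.99 on arrays 2 to 4. The highest deposited values on arrays 2 to 4 were 8.95, 6.97 and 9.76, which would lie within 16 bits on a natural log scale too. A natural log is therefore not excluded, and every fold size below assumes base 2. The normalization and software that the authors used, and the direction of the ratios, are not given in the sources used here. Array medians as deposited were 0.431, 0.765, -0.174 and 1.41 for arrays 1 to 4, so the table was not centred at 0. No spot intensities were analysed here, so signal over background is unknown for every value.

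Before the data were examined, the groups, the tests, 31 gene lists, the named-gene rule and the settings to vary were fixed. So was a direction rule: a mean correlation above 0 between arrays of opposite dye orientation means that the ratios are read as already turned to AAE13 over ccdB. It was 0.576, against 0.693 between arrays of the same orientation. Array medians beyond 0.1 from 0 called for centring each array on its median. Gene names came from the platform annotation, which names 1 gene for 4075 probes and none for 2181, which were left out. Symbols were updated through a reference table of assembly R64, used for names and gene order alone: 3939 were current, 125 older symbols were updated and 8 were kept without a match. Probes of a gene were averaged (3 genes had 2 probes), which gave 4072 genes measured on at least 3 arrays.

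Each gene's log2 ratios were tested against 0 with lmFit and eBayes in limma 3.58.1 (R 4.3.3), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Each ratio is itself the paired value of an array. Lists with at least 5 genes tested were compared with the other genes by camera with a preset inter-gene correlation of 0.01, adjusted over 31 lists. SD values are over arrays. The script was tested on 20 simulated sets of 4069 genes, each with 200 changed genes: it called 5% of changes of 0.5 on the log2 scale, 54.6% of changes of 1, 90.5% of changes of 2 and 99.1% of changes of 4, and 4.02% of its calls were false. A planted list of 20 genes shifted by 0.5 passed in 20 of 20 sets and an unchanged list in 0. The simulated arrays were drawn independently and 200 genes were changed, whereas 1011 genes were called in the data. Of the variance within genes in the data, the dye orientation held 44.0% and arrays 1 and 2 against 3 and 4 held 47.6%. Arrays 1 and 4 against 2 and 3 held 8.4%. The shares recovered and false therefore need not hold for the real gene test. The simulated genes were also drawn independently of each other, so the sets cannot show how the list test behaves when genes are correlated. In the real lists the estimated correlation ran from -0.019 (oxidative stress) to 0.73 (cytosolic ribosomal proteins). Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

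Genes were named by a fixed rule: the 8 largest rises and 8 largest falls among genes that passed with 1 sign on every array, the 2 members with the largest called change of each list that was called or had at least 2 called members, and always ACC1, FAS1, FAS2, OLE1, ACS1, ACS2, ACB1, LEU2 and TDH3. It took 76 genes. Genes of the mitochondrial genome and of the lists in the closing observations, and genes named to spell out small counts, were added after seeing the data. The settings varied were the other direction reading, a dye term, scaling of the arrays, the filter on missing values, 1 probe per gene, array weights, robust moderation, an unmoderated test, other thresholds, an estimated correlation, fry and leaving out each array. Values not centred, unnamed probes, chromosome sets and splits of the arrays into pairs were added after seeing the data.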

Results

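Transcript levels were compared between Saccharomyces cerevisiae carrying AAE13 and a control strain on 4 two-colour microarrays. AAE13 is a plant malonyl-CoA synthetase, an enzyme that makes malonyl-CoA, the building block of fatty acid chains, from malonate. Both strains carried an integrating vector with a LEU2 marker and the strong GPD (TDH3) promoter, with AAE13 in the transgenic strain and the ccdB cassette of the empty vector in the control. Cultures grew at 30 °C in drop-out medium, received 0.2 mM malonate at an optical density of 0.1, and were harvested in mid-log phase. Each array set 1 of 4 AAE13 cultures against 1 of 4 control cultures, with AAE13 labelled in the Cy5 channel on arrays 1 and 3 and in Cy3 on arrays 2 and 4. The 4 arrays limit the precision of every value below. No probe for the AAE13 transcript itself was analysed here.

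The question of the design was which yeast transcripts differ between the AAE13 strain and the vector control when malonate is supplied. Ratios are AAE13 over ccdB on the log2 scale, each array centred on its median, so that higher and lower are relative to the typical gene. The direction of the deposited ratios is not settled, since no source used here states it. The mean correlation between arrays of opposite dye orientation was 0.576 over all probes, so the arrays were read as sharing 1 direction. A correlation cannot tell AAE13 over ccdB from its inverse, or from a dye effect shared by ratios never turned. AAE13 over ccdB is called likely from the order of the strains in the series title alone. The sample titles instead name AAE13 first on the arrays of 1 dye orientation and ccdB first on the others. Read in the same way, they would mean unturned ratios with the same dye on top throughout, the other direction reading below. The signs shared by the arrays would then be a dye effect, so the reading used remains an assumption. If the ratios had been turned to ccdB over AAE13 instead, every direction below would be the opposite.

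Of 4072 named genes, 1011 passed limma's moderated test at an adjusted p under 0.05, 529 higher and 482 lower in the AAE13 strain. Of these, 1008 had the same sign on every array and 511 differed at least 2-fold (284 higher, 227 lower). The transcripts that rose most were those of the mitochondrial COX1 region, leaving out the AAP1 probe, whose gene is uncertain, and those that fell most encoded phosphate, iron and zinc transporters and enzymes of amino acid use. The count depended on single arrays, with 622 genes passing without array 1 and 428 without array 4. With the arrays not centred, an alternative chosen after seeing the data, 799 genes passed, 744 higher and 55 lower, with the median of all genes then at 0.58. Under the other direction reading, in which the ratios are taken as Cy5 over Cy3, limma called 0 genes, with 154 at an unadjusted p under 0.05.

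The COX1 transcript, which encodes a subunit of cytochrome c oxidase in the mitochondrial genome, was 181-fold higher, at 7.50 ± 0.73 (SD, n = 4; limma adjusted p = 6.93e-06). The RNA was reverse transcribed from an oligo-dT primer, and unequal labelling of RNA without poly(A) tails could not be told apart for mitochondrial transcripts. With signal over background unknown as well, fold sizes of mitochondrial genes may not reflect transcript levels. The reading frames AI1, AI2, AI3 and AI4 had log2 ratios of 7.27, 5.97, 6.78 and 6.45. They lie in introns of COX1 and so are not independent of it. The further COX1 intron frames AI5_ALPHA at -0.40 ± 0.83 (SD, n = 4) and AI5_BETA at 0.46 ± 1.40 (SD, n = 3) did not pass (limma adjusted p = 0.364 and 0.519). COX3, another cytochrome c oxidase subunit, was at 4.90 ± 0.64 and COX2 at 1.90 ± 1.17 (SD, n = 4; adjusted p = 4.91e-05 and 0.0139, limma). The probe named AAP1 had a log2 ratio of 7.67 ± 0.81 (SD, n = 3), but this symbol belongs to a nuclear gene and is also an older name of mitochondrial ATP8, so the gene it measures is uncertain. Among the other genes that passed, the most increased was ECM13, at 3.98 ± 0.29 (SD, n = 4; 15.8-fold; adjusted p = 2.47e-05). Of 17 mitochondrial genome genes tested, 7 rose and 10 did not pass, ATP6 among the latter at -0.05 ± 0.85 (SD, n = 4). COB, encoding cytochrome b, had values of 7.27, 6.85, -2.55 and -2.20 on arrays 1 to 4, and BI4, a reading frame in an intron of COB and so not independent of it, had 5.20, 5.92, -5.70 and -5.03. The other COB intron frames did not follow, with -0.72, -0.76, 1.26 and -3.12 for BI2 and -0.25, 0.68, 1.01 and -1.48 for BI3. As a set added after seeing the data, the mitochondrial genome stood apart from the other genes (camera adjusted p = 0.000138 over 17 chromosome sets; adjusted p = 0.762 with an estimated correlation).

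**Figure D1:**
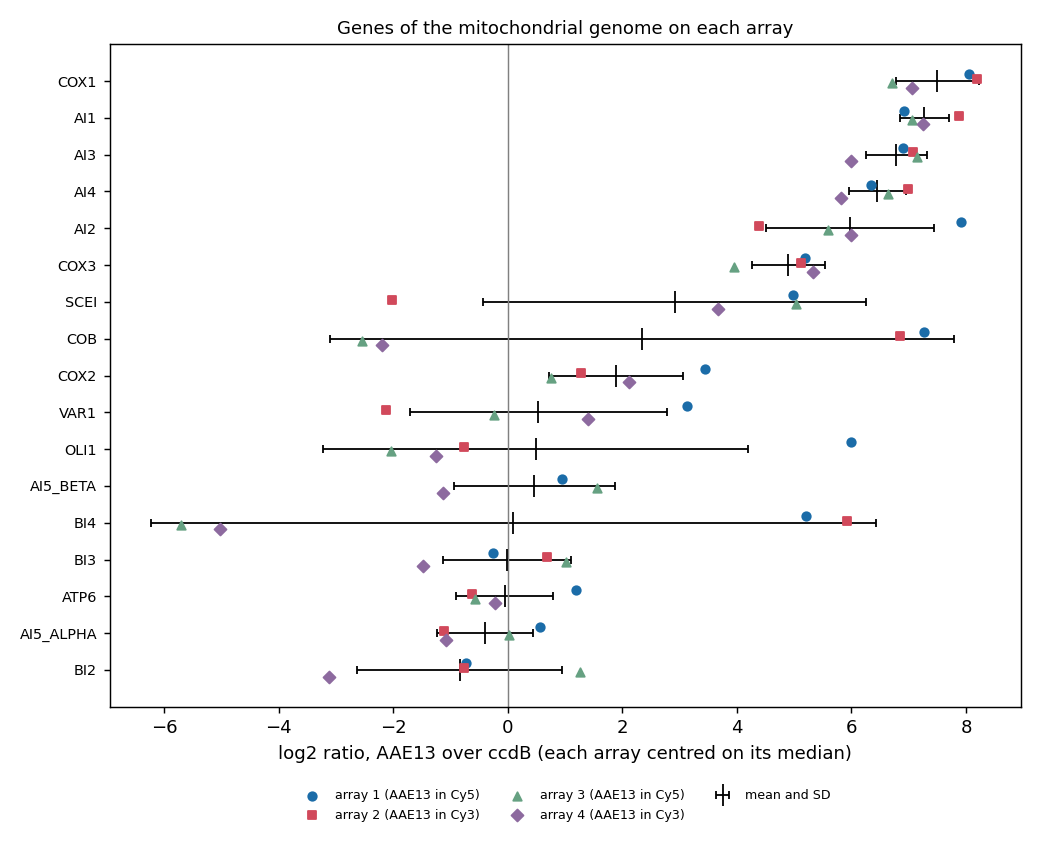
Log2 ratio of AAE13 over ccdB (x axis) for each gene of the mitochondrial genome (y axis), with a point per array, a vertical bar for the mean and a horizontal bar for the SD. COX1 lies above 6.7 on all 4 arrays, and COB lies at 7.27 and 6.85 on arrays 1 and 2 and at -2.55 and -2.20 on arrays 3 and 4.

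Nuclear genes of respiration rose together. In the list of respiratory chain and ATP synthase genes, of 35 genes tested, 30 rose, 0 fell and 5 did not pass (32 higher and 0 lower adjusted over the list alone). Its median log2 ratio was 1.38 (camera adjusted p = 1.84e-15; adjusted p = 0.434 with an estimated correlation). NDE1, an external NADH dehydrogenase, was 7.6-fold higher at 2.93 ± 0.66, and CYT1, cytochrome c1, was at 2.34 ± 0.20 (SD, n = 4; adjusted p = 0.000559 and 0.000249, limma). The respiratory list was higher with AAE13 in Cy3, its median differing by -0.84 between arrays 1 and 3 and arrays 2 and 4 (camera adjusted p = 2.01e-07 with the preset correlation, a split added after seeing the data). In the tricarboxylic acid cycle list, of 16 genes tested, 14 rose, 0 fell and 2 did not pass (14 higher and 1 lower adjusted over the list alone). The list had a median of 1.90 (camera adjusted p = 1.29e-09; adjusted p = 0.434 with an estimated correlation). Aconitase ACO1 was at 3.24 ± 0.46 and the isocitrate dehydrogenase subunit IDH1 at 2.70 ± 0.30 (SD, n = 4; adjusted p = 0.000181 and 0.000193, limma). For glycolysis and ethanol formation, of 22 genes tested, 0 rose, 4 fell and 18 did not pass (0 higher and 4 lower adjusted over the list alone), with a median of -0.63 (camera adjusted p = 0.00548; adjusted p = 0.73 with an estimated correlation), or -0.02 with the arrays not centred. PGK1, phosphoglycerate kinase, was at -1.64 ± 1.07 and PDC6, a minor pyruvate decarboxylase, at -2.15 ± 1.82 (SD, n = 4). Both lost their call without array 4, at adjusted p = 0.0843 and 0.144 in limma, PGK1 also with the arrays not centred (0.0718), and PDC6 also with a dye term (0.0796) or without array 3 (0.0525). The median of the glycolysis list was -0.48, -1.60, 0.29 and -1.04 on arrays 1 to 4, lower on both arrays with AAE13 in Cy3, and the list was not called without array 2 (adjusted p = 0.0646) or by fry (0.255).

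Genes of fatty acid synthesis, the pathway that uses malonyl-CoA, changed in part. ACC1, the acetyl-CoA carboxylase that makes the cell's own malonyl-CoA, was 2.51-fold lower at -1.33 ± 0.47 (SD, n = 4; limma adjusted p = 0.00497). The fatty acid synthase genes FAS1 and FAS2 were at -1.40 ± 0.78 and -1.51 ± 0.62 (SD, n = 4; adjusted p = 0.0131 and 0.00539, limma). All 3 were lower on every array, but with the arrays not centred they were at -0.72, -0.79 and -0.90 and did not pass (adjusted p = 0.215, 0.17 and 0.116), and FAS1 did not pass without array 4 (adjusted p = 0.0566). In the cytosolic list, of 9 genes tested, 1 rose, 3 fell and 5 did not pass (1 higher and 3 lower adjusted over the list alone). The list was not called (camera adjusted p = 0.165; adjusted p = 0.73 with an estimated correlation), and the gene that rose was the elongase gene ELO1. The fatty acid desaturase gene OLE1 was at -0.29 ± 0.10, the acetyl-CoA synthetase genes ACS1 and ACS2 at -0.39 ± 0.51 and -0.32 ± 0.82, and the acyl-CoA binding protein gene ACB1 at 0.03 ± 0.28 (SD, n = 4), and none of them passed (limma adjusted p = 0.207, 0.231, 0.463 and 0.918). LEU2, the vector marker, was at -1.29 ± 1.65 and TDH3 at -1.35 ± 1.44 (SD, n = 4). Neither passed with all arrays (limma adjusted p = 0.12 and 0.0766), and both passed without array 3 (adjusted p = 0.00999 and 0.0107), TDH3 also with a dye term (0.00818).

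**Figure D2:**
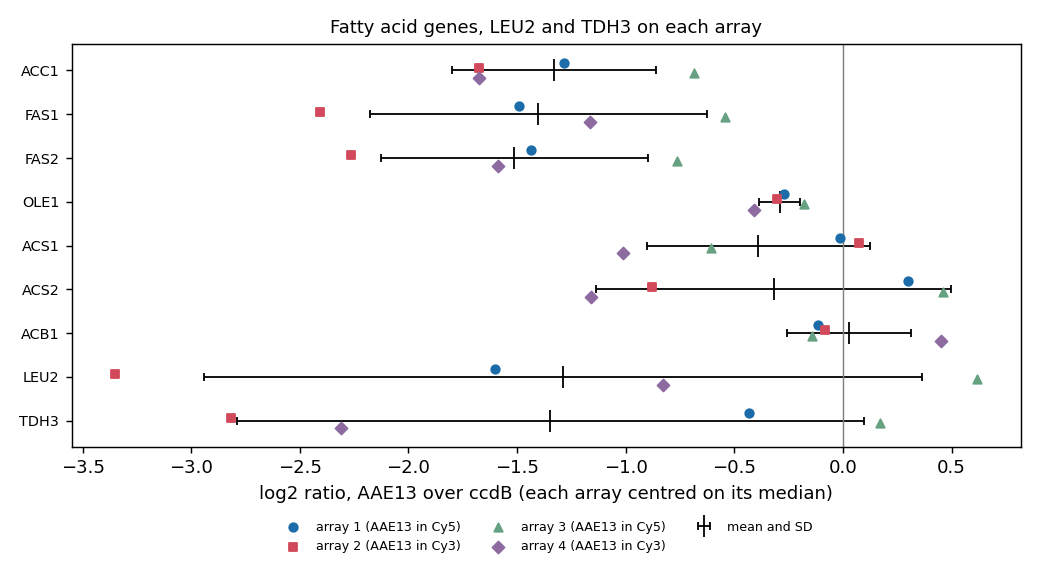
Log2 ratio of AAE13 over ccdB (x axis) for the genes of fatty acid synthesis and acyl-CoA named in advance, and for LEU2 and TDH3 (y axis), with a point per array, a vertical bar for the mean and a horizontal bar for the SD. ACC1, FAS1 and FAS2 lie below 0 on all 4 arrays, and LEU2 and TDH3 lie on both sides of 0.

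For phospholipid synthesis, of 24 genes tested, 2 rose, 11 fell and 11 did not pass (2 higher and 11 lower adjusted over the list alone). Its median log2 ratio was -0.45 (camera adjusted p = 0.0044; adjusted p = 0.467 with an estimated correlation), or 0.16 with the arrays not centred. The inositol transporter gene ITR1 was at -2.05 ± 0.60 and the phosphatidylethanolamine methyltransferase gene CHO2 at -1.80 ± 0.30 (SD, n = 4; adjusted p = 0.00167 and 0.00092, limma). Lists of other lipid steps were not called by camera with all arrays and the preset correlation, but 3 of them passed under settings that keep the direction reading. Ergosterol synthesis passed under the other reading, with the opposite sign (adjusted p = 0.0187). Triacylglycerol and steryl ester metabolism passed with array weights (adjusted p = 0.047), without array 3 (0.0488) or array 4 (0.0441) and by fry (0.022), sphingolipid metabolism by fry (0.0338), and coenzyme A and pantothenate synthesis with the arrays not centred (0.0089). For sphingolipid metabolism, of 21 genes tested, 6 rose, 3 fell and 12 did not pass (8 higher and 4 lower adjusted over the list alone), at a camera adjusted p of 0.0977, with the ceramidase gene YPC1 at 2.05 ± 0.42 and the hydroxylase gene SUR2 at 1.30 ± 0.28 (SD, n = 4). In peroxisomal beta-oxidation, of 18 genes tested, 1 rose, 6 fell and 11 did not pass (1 higher and 7 lower adjusted over the list alone), at an adjusted p of 0.252, the thiolase gene POT1 being at -2.61 ± 0.81 (SD, n = 4). For ergosterol synthesis, of 26 genes tested, 2 rose, 3 fell and 21 did not pass (2 higher and 3 lower adjusted over the list alone), at an adjusted p of 0.33. In triacylglycerol and steryl ester metabolism, of 14 genes tested, 1 rose, 1 fell and 12 did not pass (1 higher and 1 lower adjusted over the list alone), at an adjusted p of 0.0555, the gene that rose being GPD1, glycerol-3-phosphate dehydrogenase, at 2.31 ± 0.24 (SD, n = 4). For acyl-CoA synthetases and acetyl-CoA supply, of 18 genes tested, 2 rose, 3 fell and 13 did not pass (2 higher and 4 lower adjusted over the list alone), at an adjusted p of 0.408, with the aldehyde dehydrogenase gene ALD5 at 2.97 ± 1.17 (SD, n = 4). For mitochondrial fatty acid and lipoate synthesis, of 10 genes tested, 3 rose, 2 fell and 5 did not pass (3 higher and 3 lower adjusted over the list alone), at an adjusted p of 0.919. In coenzyme A and pantothenate synthesis, of 7 genes tested, 3 rose, 0 fell and 4 did not pass (3 higher and 1 lower adjusted over the list alone), at an adjusted p of 0.307, among them BAT1 and ILV3, which also belong to the branched-chain amino acid list.

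The 3 lists of amino acid synthesis were higher. For arginine and lysine, of 17 genes tested, 12 rose, 0 fell and 5 did not pass (13 higher and 0 lower adjusted over the list alone). Its median log2 ratio was 1.48 (camera adjusted p = 6.8e-08; adjusted p = 0.467 with an estimated correlation). ARG4, argininosuccinate lyase, was at 2.03 ± 0.33 (SD, n = 4). Of the methionine and sulfur genes, 24 were tested, 13 rose and 2 fell (14 were higher and 2 lower adjusted over the list alone), with a median of 0.66 (camera adjusted p = 5.51e-05; adjusted p = 0.434 with an estimated correlation), or 1.27 with the arrays not centred. MET17 was at 2.77 ± 0.81 and MET16 at 2.36 ± 0.67 (SD, n = 4). For leucine, isoleucine and valine, of 12 genes tested, 8 rose, 1 fell and 3 did not pass (10 higher and 2 lower adjusted over the list alone), with a median of 1.10 (camera adjusted p = 0.00214; adjusted p = 0.519 with an estimated correlation), or 1.71 with the arrays not centred. LEU1, isopropylmalate isomerase, had log2 ratios of 1.71, 1.50, 5.85 and 4.5 on arrays 1 to 4, and the aminotransferase gene BAT1 had 2.43, 0.99, 5.71 and 4.42. Their calls were lost without array 4 (limma adjusted p = 0.0717 and 0.0684). Purine and one-carbon genes were lower as a list; of 19 genes tested, 1 rose, 5 fell and 13 did not pass (1 higher and 11 lower adjusted over the list alone). Its median log2 ratio was -1.22 (camera adjusted p = 0.00219; adjusted p = 0.519 with an estimated correlation), or -0.61 with the arrays not centred. The list's median was -0.32, 0.02, -1.96 and -1.82 on arrays 1 to 4. IMD2, inosine monophosphate dehydrogenase, was at -3.04 ± 0.59 (SD, n = 4; limma adjusted p = 0.000419), and close copies IMD3 and IMD4 can cross-hybridise.

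The lists of iron and phosphate uptake were lower. In the iron regulon, of 21 genes tested, 1 rose, 11 fell and 9 did not pass (2 higher and 14 lower adjusted over the list alone). Its median log2 ratio was -0.95 (camera adjusted p = 2.68e-06; adjusted p = 0.434 with an estimated correlation), or -0.34 with the arrays not centred. The siderophore transporter gene SIT1 was 19.8-fold lower at -4.30 ± 0.45, and TIS11, an mRNA-binding protein gene of the iron response, was at -2.94 ± 0.24 (SD, n = 4; adjusted p = 3.91e-05 and 8.56e-05, limma). For the phosphate starvation response, of 18 genes tested, 1 rose, 5 fell and 12 did not pass (1 higher and 5 lower adjusted over the list alone), with a median of -0.36 (camera adjusted p = 0.0357; adjusted p = 0.467 with an estimated correlation), or 0.25 with the arrays not centred. That list was not called without array 4 (adjusted p = 0.0684) or with a dye term (0.0567). The phosphate transporter genes PHO89 and PHO84 were at -4.93 ± 0.64 and -3.40 ± 1.12 (SD, n = 4; adjusted p = 4.91e-05 and 0.00148, limma). The other genes with the largest falls were ARO10, a decarboxylase of amino acid breakdown, at -4.89 ± 0.26, the zinc transporter gene ZRT1 at -3.59 ± 0.61, proline oxidase PUT1 at -3.53 ± 0.77, the heat shock protein gene SSA3 at -3.39 ± 0.63 and REG2, a phosphatase subunit gene, at -3.19 ± 0.92 (SD, n = 4; adjusted p from 6.78e-06 to 0.000982, limma).

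Both stress lists were higher and both cytosolic translation lists lower by camera with its preset correlation. For heat shock and general stress, of 37 genes tested, 15 rose, 2 fell and 20 did not pass (19 higher and 4 lower adjusted over the list alone), with a median of 0.61 (camera adjusted p = 5.98e-05; adjusted p = 0.434 with an estimated correlation), or 1.22 with the arrays not centred. Those that rose were CTT1, TSL1, SOL4, PNC1, TPS2, GPH1, PGM2, HSP78, GSY2, TPS1, TPS3, MSC1, GPP2, GLC3 and NTH1. Those that fell were SSA3 and YDJ1. HSP78 was the only gene named HSP that passed, so the call does not stand for heat shock proteins in general. Catalase CTT1, which also belongs to the oxidative stress list, was at 2.32 ± 0.29 (SD, n = 4), against the fall of SSA3. For oxidative stress, of 17 genes tested, 5 rose, 0 fell and 12 did not pass (5 higher and 0 lower adjusted over the list alone), with a median of 0.23 (camera adjusted p = 0.036; adjusted p = 0.434 with an estimated correlation), or 0.84 with the arrays not centred, and the list was not called without array 1 (adjusted p = 0.0693) or with a dye term (0.0515). Among cytosolic ribosomal proteins, of 135 genes tested, 1 rose, 39 fell and 95 did not pass (1 higher and 63 lower adjusted over the list alone). The median of the list was -0.67 (camera adjusted p = 2.64e-13; adjusted p = 0.551 with an estimated correlation). Array medians of that list were -0.94, -1.38, -0.15 and -0.27, the overall median was -0.060 with the arrays not centred, and many members have near-identical copies that can cross-hybridise. For ribosome biogenesis, of 52 genes tested, 0 rose, 16 fell and 36 did not pass (0 higher and 16 lower adjusted over the list alone), with a median of -0.44 (camera adjusted p = 4.36e-05; adjusted p = 0.551 with an estimated correlation), or 0.17 with the arrays not centred. NSR1, nucleolin, was at -2.20 ± 0.88 (SD, n = 4).

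Markers of other cell states were tested in the same way. For mating type and pheromone response, of 27 genes tested, 2 rose, 5 fell and 20 did not pass (2 higher and 5 lower adjusted over the list alone), with a median of -0.43 (camera adjusted p = 0.036; adjusted p = 0.434 with an estimated correlation), or 0.18 with the arrays not centred. The call was lost without array 2 or array 4 (adjusted p = 0.0561 and 0.0684) and with the arrays not centred (0.0676). In sporulation and meiosis, of 27 genes tested, 0 rose, 8 fell and 19 did not pass (0 higher and 11 lower adjusted over the list alone), with a median of -0.44 (camera adjusted p = 0.00566; adjusted p = 0.434 with an estimated correlation), or 0.17 with the arrays not centred. Histone genes (1 of 10 lower; adjusted p = 0.544) and mitochondrial ribosomal protein genes (3 of 60 higher; adjusted p = 0.0997) were not called as lists. Nor were hexose transport (2 higher and 4 lower of 14; adjusted p = 0.772), biotin and thiamine metabolism (4 lower of 22; 0.0539), weak acid and multidrug response (8 higher and 5 lower of 22; 0.544), the glyoxylate cycle and gluconeogenesis (4 higher and 3 lower of 13; 0.772) and auxotrophic marker genes (3 higher and 2 lower of 8; 0.763). Adjusted over the list alone, hexose transport had 2 genes higher and 4 lower, biotin and thiamine 0 and 6, multidrug response 9 and 7, glyoxylate 4 and 3, and auxotrophic markers 3 and 2. Histones and mitochondrial ribosomal proteins had 0 and 0. The auxotrophic list had a median of -0.36 and a mean of 0.29, and the glyoxylate list 0.22 and -0.069, so that median and mean differed in sign. Of the auxotrophic markers, MET17, LYS2 and HIS3 were called higher and ADE2 and URA3 lower. A list test for a shared direction does not show opposite changes of single markers, so it does not mean that the markers were alike in the strains. With the direction reading kept, biotin and thiamine metabolism passed with a dye term (adjusted p = 0.0437), with array weights (0.044), with unnamed probes included (0.0407) and without array 3 (0.00515). Mitochondrial ribosomal proteins did so with a dye term (0.0448) and without array 1 (0.0442) or array 3 (0.0129).

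In all, 16 of 31 lists were called by camera with its preset correlation, 7 higher and 9 lower, and 0 with an estimated correlation, where 2 lists had an unadjusted p under 0.05. By fry, which tests whether a list moves 1 way without comparing it to other genes, 13 lists passed, without those of glycolysis, leucine, purines, ribosome biogenesis and cytosolic ribosomal proteins. With a dye term 14 of the 16 lists kept their call. Under the other direction reading camera called 8 lists, all with the opposite direction. These were mitochondrial ribosomal proteins (median -0.27; adjusted p = 2.62e-08), glycolysis (0.55; 1.61e-08), and hexose transport (0.41, adjusted p = 0.00484). Respiration (-0.42), histones (-0.33) and cytosolic ribosomal proteins (0.13) passed at adjusted p = 0.0151 each. The other 2 were ergosterol (0.15, adjusted p = 0.0187) and biotin and thiamine (0.19, adjusted p = 0.0374). Across genes, the mean correlation between pairs of arrays was 0.646 (range 0.451 to 0.736), and genes are not independent replicates.

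**Figure D3:**
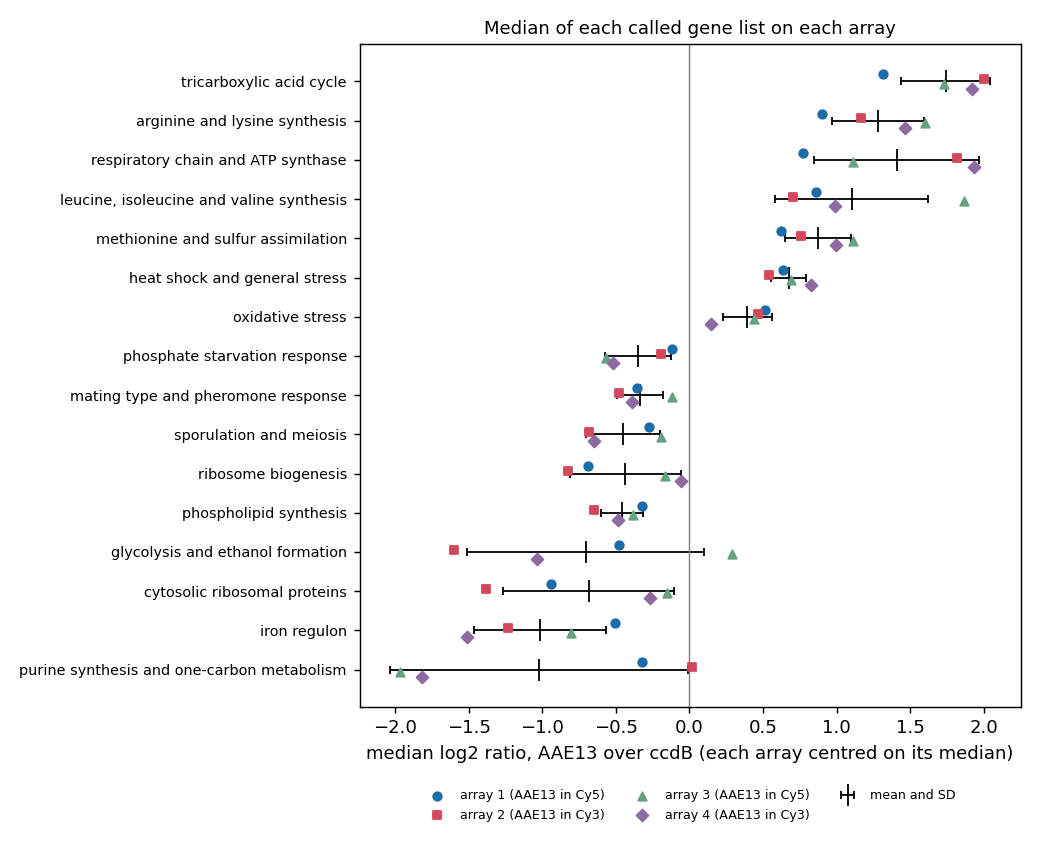
Median log2 ratio of AAE13 over ccdB (x axis) of the 16 gene lists called by camera with its preset correlation (y axis), with a point per array, a vertical bar for the mean of the array medians and a horizontal bar for their SD. The tricarboxylic acid cycle list lies above 1.3 on all 4 arrays, and the purine list lies at -0.32 and 0.02 on arrays 1 and 2 and at -1.96 and -1.82 on arrays 3 and 4.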

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

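All tests of explanations in this part were chosen after the values they use had been seen. Of 106 results with values on all 4 arrays, 4 had an array far from the other 3, where chance gives about 5.3. COX3 was at 3.95 on array 3 and between 5.12 and 5.33 on the others. The ribosomal protein gene MRPL4 was at 0.50 on array 2 and between 0.80 and 0.81 on the others. ACB1 was at 0.45 on array 4 and between -0.14 and -0.08 on the others. The median of the peroxisomal beta-oxidation list was -0.27 on array 4 and between -0.07 and -0.06 on the others.

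The real arrangement of signs called 1011 genes and the highest of the other 7 sign patterns of the 4 arrays called 1, so 1 of 8 patterns gave as many. With 8 patterns the share cannot fall under 0.125, too few for a share under 0.05. For lists, 16 were called, the highest other pattern gave 15, and again 1 of 8 gave as many.

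COX1 and 6 other mitochondrial genome genes, 4 of them frames inside COX1, were called higher, yet COB and BI4, a frame inside COB and so no separate transcript, rose on arrays 1 and 2 and fell on arrays 3 and 4, which the COB intron frames BI2 and BI3 did not. Under the direction reading used, a dye effect equal on all arrays cancels from the means of the genes called higher, while under the other direction reading 1 sign on every array would itself be a dye effect. Unequal labelling of RNA without poly(A) tails would, if its yield were shared by all of them, move these transcripts together on an array. Of the 7 loci other than COX1, 2 (COB and OLI1) lay beyond 1 log2 unit on the other side of 0 from COX1 on both arrays 3 and 4. That argues against a shared difference in yield for these 2, but not against one that differs between transcripts. With signal over background unknown, and with fewer than 4 of 7 loci opposed, unequal labelling cannot be told apart for the set. A difference in mitochondrial genome content between cultures may remain. Neighbouring genes were more alike than in random orders over 17 genes (one-sided permutation p = 0.0288). That test takes frames inside COX1 and COB as neighbours of their own transcript. Over 8 separate loci the mean difference between neighbours was 2.61 against 2.95 over all orders (exact one-sided permutation p = 0.272), which decides nothing. The order was taken as linear, so the end loci COX1 and COX3, both called higher, were not compared with each other. Means over arrays were used, which cannot show a difference in content that varies between arrays.

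Arrays 1 and 2 differed from arrays 3 and 4 in a further set of genes, with 6 genes called for that split by limma (450 at an unadjusted p under 0.05): COB, BI4, GAP1, MGA1, PDC6 and ADE17, named after their values were seen. The purine list was higher on arrays 1 and 2 by 1.52 (camera adjusted p = 1.01e-11) and the leucine list lower by 1.43 (8.31e-06). Cytosolic ribosomal proteins were lower by 0.98 (1.57e-34) and ribosome biogenesis by 0.59 (4.68e-07), among 9 lists that passed for this split. These p-values rest on the preset correlation, and no estimated correlation was used for the splits. Arrays 1 and 4 against 2 and 3 gave 16 called lists, with 0 genes called by limma and 8 at an unadjusted p under 0.05. The preset test can thus call many lists where no gene is called, so small list p-values are weak evidence here. A dye effect equal on all arrays cancels from the contrast of arrays 1 and 2 with 3 and 4, so that split is no test of dye bias. A difference in culture or medium between replicates could account for the 6 genes, but no label gives a batch, so it cannot be told apart from variation between cultures.

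Glycolysis genes were lower with AAE13 in Cy3 by a median of 1.09 (camera adjusted p = 2.43e-08 with the preset correlation), 1 of 10 lists that passed for the dye orientation. The mark set for residual dye bias was at least 18 of 22 genes lower on both Cy3 arrays than on both Cy5 arrays. It was chosen after the values had been seen and does not follow from dye bias, so missing it is no evidence against dye bias. The count was 15 of 22, where chance gives 16.7% of genes. Over all genes the share was 22.4%, with 29.6% higher on both Cy3 arrays, so that 52.0% had dye pairs that did not overlap against 33.3% by chance, and the orientation held 44.0% of the variance within genes, while arrays 1 and 2 against 3 and 4 had 39.4% and held 47.6%. No gene was called for dye orientation by limma, 0 with 719 at an unadjusted p under 0.05, and without intensities residual dye bias may remain and cannot be told apart from differences between the cultures.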

How the results depend on the processing

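Values not centred, unnamed probes and the mitochondrial count were alternatives chosen after seeing the data. Of 1011 genes called, 950 kept their call and sign with a dye term (1276 called), 990 with scaled arrays, 987 with array weights, 1007 with robust moderation and 583 not centred. The unmoderated test called 143 genes. The fits at other thresholds also held a dye term, and called 356 genes at an adjusted p under 0.01 and 1836 under 0.10. Leaving out an array gave 428 to 1044 genes, 14 to 19 lists, correlations of 0.605 to 0.676 and 6 to 8 mitochondrial genome genes, with 1 array fewer each time. Of 70 named genes called, 18, all lower, lost the call not centred, and 58 kept the call without any 1 array. The unmoderated test ended 48 of the 70 calls, and an adjusted p under 0.01 with a dye term ended 18. Requiring 2 or more arrays removed no gene and moved nothing. With an estimated correlation 0 lists were called. The list of mitochondrial fatty acids, never called, changed its test direction at medians of -0.18 with a dye term and by fry, and between -0.16 and 0.0158 without an array, the glyoxylate list at 0.83 not centred and -0.12 without array 2 (range -0.12 to 0.27 without an array), and hexose transport at 0.19 and 0.0875 without arrays 2 and 4 (range -0.35 to 0.19). Not centred, OLE1, ACS1 and ACS2 were at 0.32, 0.22 and 0.29, and ACB1 was at -0.11 without array 4 (range -0.11 to 0.0854), none of them called. The cause was not tested. Beyond the fit used, which is paired by array, no paired analysis was possible because each ratio already pairs 2 cultures. Signal over background, which limits weak spots, is unknown.

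Under the other direction reading, which would measure a dye effect if the reading used is right, 0 genes, 8 lists and 0 mitochondrial genome genes were called and the mean correlation was -0.181. Of the 76 named genes, 27 kept their sign and lost the call, and are not listed here, among them AI2 at 0.78, BAT1 at 0.68 and REG2 at -0.71. The other 49 changed sign. Their log2 ratios then were -3.15 for AAP1, -0.12 for COX1, -0.29 for AI1, -0.33 for COX3, -0.19 for ECM13, 0.25 for PHO89, 0.24 for ZRT1, 0.0211 for SSA3, 0.41 for FAS2 and 0.38 for FAS1. Further values were -0.33 for LIP5, 0.0837 for CEM1, 0.26 for ITR1, 0.24 for CHO2, -0.24 for ERG28, -0.0854 for YPC1, 0.25 for POT1, 0.26 for SPS19, -0.16 for ACO1 and -0.16 for IDH1. Next came 0.13 for PCK1, -0.15 for CYT1, 0.15 for PDC6, 0.73 for PGK1, 0.64 for HXT10, 0.38 for HXT2, -0.0174 for ARG7, -0.0756 for ARG4, -0.41 for MET16 and 0.47 for IMD2. Others were 0.0916 for TIS11, 0.44 for THI4, 0.18 for PHO3, -0.0671 for CTT1, -0.0709 for CCP1, -0.0496 for YRO2, -0.10 for GRE2, 0.63 for NSR1, 0.29 for UTP22 and 0.24 for SPR28. The rest of the 49 were 0.19 for RPS9A, -0.11 for MRP2, 0.35 for ACC1, 0.0657 for OLE1, 0.0792 for ACS1, 0.70 for ACS2, -0.16 for ACB1, 0.80 for LEU2 and 1.22 for TDH3. Of the 31 lists, 6 kept their test direction and stayed without a call. A further 5 kept it and lost the call, with medians of 0.28 for leucine, -0.014 for arginine and lysine, 0.12 for methionine, 0.0211 for heat shock and -0.053 for oxidative stress. The other 20 changed test direction. Their medians then were 0.35 for fatty acid synthesis, 0.057 for acetyl-CoA supply, 0.12 for phospholipids, 0.15 for ergosterol, 0.0683 for beta-oxidation, -0.16 for the acid cycle and -0.0322 for glyoxylate. Further medians were -0.42 for respiration, 0.55 for glycolysis, 0.41 for hexose transport, -0.0898 for purines, 0.0005 for phosphate, 0.11 for iron and 0.19 for biotin and thiamine. The remaining medians of the 20 were 0.0526 for ribosome biogenesis, 0.0556 for mating, 0.15 for sporulation, -0.33 for histones, 0.13 for ribosomal proteins and -0.27 for mitochondrial ribosomal proteins. That alternative changes the sign on 2 arrays, so that a gene's mean reflects the difference between dye orientations.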

Other observations

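The gene groups in this part were drawn up after the most changed genes had been seen, so their counts are descriptions without a list test. Of the zinc genes, 9 were tested, 0 rose and 7 fell, COT1 and ZRC1 being at 0.30 ± 0.18 and 0.08 ± 0.20 (SD, n = 4), with the transporter genes ZRT1 and ZRT2 at -3.59 ± 0.61 and -1.82 ± 0.45 and the regulator gene ZAP1 at -1.57 ± 1.07 (SD, n = 4; adjusted p = 0.000209, 0.00152 and 0.0215, limma). For copper uptake and binding, of 11 genes tested, 0 rose and 6 fell, with the transporter gene CTR1 at -1.91 ± 0.39 (SD, n = 4). The metallothionein genes CUP1-1 and CUP1-2, near-identical copies that cannot be separated by hybridisation, were at -1.69 and -1.66. Of the sodium and potassium transport genes, 6 were tested, 0 rose and 3 fell, with ENA1 at -3.17 ± 1.04 (SD, n = 4).

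In nitrogen source use, of 25 genes tested, 2 rose and 13 fell. The regulator gene DAL80 was at -2.06 ± 0.55, glutamine synthetase GLN1 at -2.28 ± 0.78 and the amino acid permease gene AGP1 at -2.02 ± 0.70 (SD, n = 4; adjusted p = 0.00144, 0.0021 and 0.00248, limma), while UGA2 of the GABA pathway was at 2.09 ± 0.47 (SD, n = 4). The permease gene GAP1 had -0.71, -0.78, -4.02 and -4.40 on arrays 1 to 4. For fusel alcohol formation from amino acids, of 9 genes tested, 1 rose and 3 fell, ARO10 and the aminotransferase gene ARO9 among the latter. For glycerol formation and export, of 9 genes tested, 5 rose and 1 fell, and the phosphatase genes GPP1 and GPP2 went opposite ways, at -1.83 ± 0.28 and 0.97 ± 0.36 (SD, n = 4).

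Among probes without a gene name, which the comparisons leave out, 530 of 2181 passed in a limma fit of all probes, 307 higher and 223 lower.

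A hypothesis from the mitochondrial transcripts is that mitochondrial function was impaired in the control cultures, which may raise retrograde and drug resistance genes there. CIT2, DLD3 and PDR5 were looked at first and all 3 were lower in the AAE13 cultures. Those 3 were chosen because they were low, so they were left out of the test of mitochondrial dysfunction in the control cultures, as was the earlier count of 4 lower of 8 genes, which included them. Of the 5 other such genes, with at least 4 lower set as the mark for this hypothesis and at least 4 higher against it, 1 was lower (PYC1) and 0 were higher, and PDR3, SNQ2, PDR15 and YOR1 did not pass (limma adjusted p = 0.0664, 0.0674, 0.552 and 0.178), which leaves it undecided. All of these limits were set after the values had been seen.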
